A study of Homo sapiens with 12 samples.

How the data were processed

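RNA was measured by sequencing in 12 libraries of 22Rv1, a human prostate cancer cell line derived from a xenograft tumour. Per the labels, 3 libraries came from cells given siRNA against ETS1, 3 from the controls of that experiment, 3 from cells given siRNA against ZNF783 and 3 from the controls of that second experiment. Groups and replicate numbers were taken from the labels of each sample. The libraries were made from total RNA with a directional (strand-marking) kit, per the labels' protocols. Neither the siRNA sequences nor the time of harvest is given in the sources used here.

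The deposited values are raw read counts per gene, in 1 table for each knockdown, and were not normalized. Per the file headers, paired-end alignments were counted over exons and summed by gene identifier with featureCounts 2.0.1, against a GRCh38 annotation of release 107. The same headers show no strand option, so reads from a gene and from an overlapping gene on the opposite strand were counted without telling the strands apart. Values of such genes are uncertain. The header names of the alignment files end in "hisat", but the aligner's version is not given in the sources used here. The build hg38 is named in the submitters' processing notes. Each table holds 61860 genes, of which 61757 (99.8%) were matched to a symbol by identifier. No column of values was left unmapped. Genes encoded by the mitochondrial genome have 0 counts in all 12 libraries, so nothing is said about them.

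Total counts ran from 13518177 to 48996691 per library, so that 3 counts, taken as the floor for an undetected gene, correspond to 0.0607 to 0.222 CPM, the counts scaled to a library of 1e+06. Floors and counting intervals cover counting error only, since reads amplified by PCR are not independent molecules. Replicates were compared with a chi-square test of their counts before use, and no pair differed as little as sampling noise alone would give, so none was merged.

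Each knockdown was tested against its own controls with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's default expression filter, libraries were scaled by trimmed mean of M values (TMM), and a robust quasi-likelihood F test was fitted with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. Levels are TMM-scaled CPM as mean ± SD over the libraries of a group. Standard errors of log2 fold changes were obtained from the F statistic. The effects of the 2 siRNAs, each measured in its own experiment, were compared with the same tool in 1 fit of all 12 libraries. The contrast was that of the 2 knockdown effects. The overlap of called genes was set against independent lists with a 1-sided Fisher exact test across genes, which are not independent replicates.

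A set of 35 gene lists, covering the cell cycle, RB and CDK4/6, ETS factors, stress responses, metabolism, cell identity and others, was fixed before the data were examined. Lists with at least 5 tested members (34 of 35, the mitochondrially encoded list being the exception) were tested with camera (limma 3.58.1), which asks whether the genes of a list shift against all other genes. It was run with an inter-gene correlation of 0.01, and again with a correlation estimated from the data for each list. The estimated correlation was applied over all libraries, without ETS1 siRNA replicate 1 and with the GC and length correction, while other settings used the preset one only. P-values were adjusted over the lists, and for each list the members called over all genes and those called when adjusted over the list alone were counted.

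The genes named were chosen by a rule that was also fixed before the data were examined. ETS1, ZNF783, RB1 and 10 further genes, mostly of the cell cycle, were fixed to be named in every comparison. Some of the genes and lists fixed or picked this way are not reported here. To these come the 10 genes with the highest and the 10 with the lowest log2 fold change among called genes with a mean of at least 10 CPM and no overlap between the groups, leaving out clone-based, LINC, LOC, antisense and pseudogene symbols. From each list described, up to 4 members with the smallest adjusted p are named. For the difference between the siRNAs the 5 highest and 5 lowest called genes are named, and for genes called with both siRNAs the 5 with the largest smaller fold change in each direction. Coordinates and gene properties come from the GENCODE release 29 annotation of GRCh38, given 1-based; 97.2% of the genes tested with ETS1 siRNA had a GC content and length.

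The alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors, library size alone, no expression filter, a filter of 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of all 12 libraries together, stricter thresholds (adjusted p below 0.01, or at least a 2-fold change), and leaving out each library. Added after the data were seen were a correction of each library for GC content and transcript length (natural splines with 6 degrees of freedom), that correction without ETS1 siRNA replicate 1, limma-voom with sample quality weights, the overlap without ETS1 siRNA replicate 1, and the settings applied to the lists in the difference between the siRNAs.

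The tests were run first on simulated counts drawn from the means, dispersions and totals of these libraries, with 200 genes changed by 1.25-, 1.5- or 2-fold. For ETS1 siRNA (19281 genes) edgeR recovered 4.48%, 71.6% and 98.5% of these, with 8 unchanged genes called; DESeq2 recovered 20.9%, 88.1% and 100% with 42 unchanged genes called. For ZNF783 siRNA (17405 genes) edgeR recovered 94.0%, 100% and 100%, with 10 unchanged genes called. For the difference between the siRNAs (19235 genes) the shares were 7.46%, 62.7% and 97.0%, with 6 unchanged genes called. In simulations with a GC trend added to 1 library, edgeR without correction recovered 0%, 40.3% and 93.9% for ETS1 siRNA and 19.4%, 80.6% and 100% for ZNF783 siRNA, and the corrected fit recovered 2.99%, 70.1% and 100% for ETS1 siRNA and 88.1%, 100% and 100% for ZNF783 siRNA. Camera recovered the 1 raised list of each knockdown's simulation and called 0 others. The simulated genes were drawn independently of each other, so this cannot show how many lists are called falsely where genes vary together. The recovered shares describe the fits of all libraries of a comparison. With ETS1 siRNA a 1.25-fold change was mostly out of reach of that fit. With ZNF783 siRNA it was mostly detected unless 1 library carried a GC trend of that size.

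For the closing observations, 3' untranslated regions (UTRs) from the GENCODE annotation were searched for every 7-base site. The scan covered 10126 genes of the ETS1 experiment and 10338 of the ZNF783 experiment, each with a mean of at least 8 CPM and a UTR of at least 50 bases (94.1% of the expressed genes in both). Log2 differences were first adjusted for the GC content and length of the transcript and of the UTR, and a z value compared genes with a site to those without it. This part used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.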

Results

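Gene expression was measured in 22Rv1 human prostate cancer cells, in a study concerned with phosphorylated RB, the transcription factor ETS1 and the response to CDK4/6 inhibitors. The 12 libraries form 4 groups of 3: ETS1 siRNA with its controls, and siRNA against ZNF783, a zinc finger protein, with separate controls. The deposited values are raw counts per gene. Total counts were 22958421, 48996691 and 34356594 in ETS1 siRNA replicates 1 to 3 and 30068026, 29817308 and 41966577 in their controls. They were 22544431, 17476409 and 13518177 in ZNF783 siRNA replicates 1 to 3, and 14763408, 14789906 and 17404100 in their controls. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

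The targeted genes were examined first. ETS1 (ENSG00000134954, GRCh38 chromosome 11, 128458761 to 128587558, minus strand) had 0, 3 and 0 counts in the ETS1 siRNA libraries and 0, 1 and 0 in their controls. In the other experiment it had 0, 1 and 1 counts with ZNF783 siRNA and 1, 0 and 1 in the controls. All values lie at or below the floor of 3 counts, in the controls too. No fold was therefore computed, and a loss of ETS1 transcript could not be measured. In the 3 ETS1 controls the upper 95% counting limits were 0.123, 0.187 and 0.0879 CPM by library size. Changes seen with ETS1 siRNA therefore cannot be tied to a loss of ETS1 transcript from these counts. ZNF783 (ENSG00000204946, chromosome 7, 149262171 to 149297302, plus strand) stood at 28.7, 27.4 and 28.0 CPM with ZNF783 siRNA (28.0 ± 0.629, SD, n = 3) and at 33.8, 34.9 and 35.7 CPM in its controls (34.8 ± 0.91, n = 3). It fell to 80.5% of control (log2 fold change -0.31, SE 0.055, adjusted p = 2.46e-05, edgeR), lower in 3 of 3 libraries. In the fit of all 12 libraries the fall did not pass (-0.32, adjusted p = 0.145). The gene overlaps 1 other annotated gene, with which reads may be shared. In the ETS1 experiment ZNF783 measured 12.5, 18.7 and 18.5 CPM with ETS1 siRNA against 21.6 ± 0.678 in the controls (n = 3). The log2 fold change was -0.38 (SE 0.15, adjusted p = 0.258, edgeR). It passed without ETS1 siRNA replicate 1 (-0.23, adjusted p = 0.00146) and with limma-voom and quality weights on all 6 libraries (-0.23, adjusted p = 0.0151). The latter weighted ETS1 siRNA replicate 1 at only 0.0931. The effects of the 2 siRNAs on ZNF783 were not found to differ (0.05, SE 0.16, adjusted p = 0.925, edgeR). A fall particular to its own siRNA was therefore not shown.

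**Figure D1:**
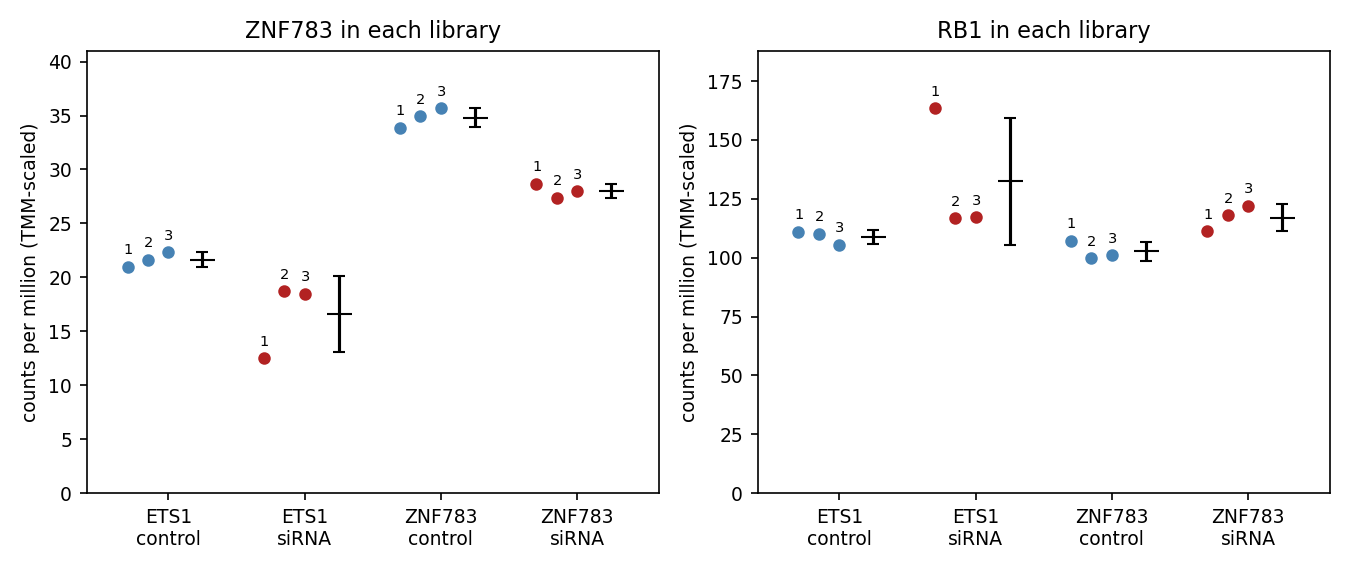
TMM-scaled CPM of ZNF783 (left) and RB1 (right) in each of the 12 libraries (points, numbered by replicate) with the group mean and SD (bars), on linear axes that start at 0. The 3 ZNF783 siRNA libraries lie at 27.4 to 28.7 CPM of ZNF783 against 33.8 to 35.7 in their controls.

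The first comparison asked which transcripts differ when ETS1 is targeted. DIO2, the deiodinase that makes active thyroid hormone, rose from 10.3 ± 0.166 to 19.96 ± 2.08 CPM (SD, n = 3 per group; log2 fold change 0.95, SE 0.093, adjusted p = 0.0426). CDK14, a cyclin-dependent kinase that acts with cyclin Y, rose from 59.8 ± 1.74 to 96.4 ± 3.95 CPM (0.69, SE 0.059, adjusted p = 0.0426). GFPT1, the first enzyme of hexosamine synthesis, rose from 172 ± 3.3 to 246 ± 2.62 CPM (0.51, SE 0.047, adjusted p = 0.0426). CRIP2, a LIM domain protein, fell from 131 ± 5.84 to 68.4 ± 7.74 CPM (-0.93, SE 0.091, adjusted p = 0.0426). MARCKSL1, an actin-binding protein, fell from 189 ± 0.711 to 117 ± 4.02 CPM (-0.70, SE 0.051, adjusted p = 0.0363). The others called were DCBLD2 (0.64, adjusted p = 0.0426) and BLOC1S6 (0.55, adjusted p = 0.0438), which rose, and the fibronectin receptor subunit ITGA5 (-0.55, adjusted p = 0.0426) and the SUMO-activating enzyme subunit SAE1 (-0.53, adjusted p = 0.0453), which fell. These 9 (5 higher, 4 lower) were all the genes called among 19542 tested with edgeR, 0 of them by 2-fold or more. An unadjusted p under 0.05 was found for 3535, and DESeq2 called 734 genes and limma-voom 23. With scaling by library size alone 13 were called, 9 higher and 4 lower. With a correction for GC content and length GFPT1 (0.33, adjusted p = 0.138), DCBLD2 (0.51, adjusted p = 0.0565) and MARCKSL1 (-0.55, adjusted p = 0.0552) lost their calls. DIO2 (chromosome 14, 80197527 to 80387757, minus strand), DCBLD2 and ITGA5 overlap annotated genes on the opposite strand, and their values are uncertain because counting ignored strand. CRIP2 lies on chromosome 14 at 105472962 to 105480170, plus strand.

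The genes of the RB axis, KLK3 and MYC did not pass with edgeR over all 6 libraries. CCND1, encoding the cyclin D1 partner of CDK4/6, had a log2 fold change of -0.24 (adjusted p = 0.103), CDK4 of -0.31 (adjusted p = 0.397), and CDK6 of 0.27 (adjusted p = 0.277). The CDK inhibitor genes CDKN1A and CDKN1B stood at -0.48 (adjusted p = 0.105) and 0.13 (adjusted p = 0.271), CCNE1 at 0.12 (adjusted p = 0.425) and E2F1 at 0.02 (adjusted p = 0.942). RB1 (chromosome 13, 48303726 to 48599436, plus strand) stood at 163, 117 and 117 CPM with ETS1 siRNA against 109 ± 2.92 in the controls (0.28, adjusted p = 0.31). KLK3, which encodes prostate-specific antigen, had a value of -0.08 (adjusted p = 0.741) and MYC of 0.06 (adjusted p = 0.705). On the same 6 libraries DESeq2 called CCND1 (adjusted p = 0.000873) and CDKN1A (adjusted p = 0.000783) as lower, and the fit of all 12 libraries did so too (adjusted p = 0.000993 and adjusted p = 0.00155). Limma-voom with quality weights called both as lower (adjusted p = 2.16e-05 and adjusted p = 2.3e-05). It also called CDK6 (0.13, adjusted p = 0.0333) and E2F1 (0.14, adjusted p = 0.032) as higher. Each of these settings has a limit. In the ETS1 simulation DESeq2 called 42 unchanged genes, against 8 with edgeR. The fit of all 12 libraries used a smaller coefficient of variation between replicates (0.0795) than the ETS1 libraries alone gave (0.107, edgeR). The quality weights put ETS1 siRNA replicate 1 at 0.0931, against 1.24 to 1.98 for the other libraries.

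ETS1 siRNA replicate 1 stood apart from replicates 2 and 3. The chi-square of its counts per degree of freedom was 40.3 against replicate 2 and 38.9 against replicate 3, compared with 1.82 between replicates 2 and 3 and 1.36 to 2.93 in the other groups. Without it, a setting fixed beforehand for every library, 4649 of 20237 genes were called (2016 higher, 2633 lower), 52 of them by 2-fold or more, and all 9 genes above were among them in the same direction. Leaving out ETS1 siRNA replicate 2 or 3, or control replicate 1, 2 or 3, gave 0 calls each (edgeR, 1775 to 3851 genes with an unadjusted p under 0.05). Without replicate 1 TPM4, an actin-binding tropomyosin, rose from 165 ± 4.59 to 300 ± 8.71 CPM (0.86, SE 0.030, adjusted p = 1.33e-30). The drug efflux pump gene ABCC1 rose by 0.94, and the KRAB zinc finger genes ZNF678, ZNF681, ZNF267 and ZNF138 rose by 0.74, 0.67, 0.67 and 0.65. MIR924HG and HABP4 rose by 0.66 each. Among those that fell were CRIP2 (-0.85, adjusted p = 5.13e-26), the homeobox gene DLX2 (-0.79), OTOP3 (-0.65), endothelin EDN2 (-0.64), STAT5A (-0.62), ARL2 (-0.60), NTNG2 (-0.59), RAB3A (-0.57) and ID2 (-0.57), an inhibitor of helix-loop-helix factors. CCND1 (-0.24, adjusted p = 1.65e-10), CDKN1A (-0.39, adjusted p = 5.64e-16) and CDK4 (-0.11, adjusted p = 0.00892) then fell, and E2F1 (0.14, adjusted p = 0.00142), CDK6 (0.11, adjusted p = 0.00265) and RB1 (0.10, adjusted p = 0.0233) rose. With the GC and length correction as well, the value of RB1 with ETS1 siRNA was -0.02 (adjusted p = 0.76) and that of CDK4 with ETS1 siRNA -0.05 (adjusted p = 0.209), so these 2 calls did not hold. E2F1 then stood at 0.23 (adjusted p = 2.4e-08). CDKN1B (0.10, adjusted p = 0.0153) passed narrowly, while CCNE1 (adjusted p = 0.067), MYC (adjusted p = 0.207) and KLK3 (adjusted p = 0.6) did not. TPM4, MIR924HG, HABP4, RAB3A, ID2, CCND1, CDK4, CDK6 and CDKN1A overlap genes on the opposite strand.

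Of the 34 lists tested with ETS1 siRNA, 11 were called over all 6 libraries, 8 lower and 3 higher, and 0 of the 11 held with a correlation estimated from the data. Cytosolic ribosomal protein genes (56 members, for example RPL23 at -0.32, adjusted p = 0.108) were lower, with a median log2 fold change of -0.32 and adjusted p = 9.04e-20, or adjusted p = 0.463 with an estimated correlation. When adjusted over the list alone 26 members fell and 0 rose. Nuclear genes of the respiratory chain (35 members, COX5A -0.42, adjusted p = 0.119) were lower at a median of -0.28 (adjusted p = 4.25e-07; adjusted p = 0.589 with an estimated correlation), with 0 members passing over the list alone. Genes of glycolysis and the hypoxia response (34 members, the glycolytic enzyme gene TPI1 -0.58, adjusted p = 0.0571) were lower at -0.16 (adjusted p = 4.25e-07; adjusted p = 0.327 with an estimated correlation), with 1 member falling over the list alone. The list of endoplasmic reticulum chaperones (21 members, HSPA5 0.24, adjusted p = 0.156; DNAJB11 0.29, adjusted p = 0.13) was higher at 0.11 (adjusted p = 0.00157; adjusted p = 0.256 with an estimated correlation), with 7 members rising and 0 falling when adjusted over the list alone. Genes of G2 and mitosis (40 members, TOP2A 0.27, adjusted p = 0.143) were higher at 0.16 (adjusted p = 0.000331; adjusted p = 0.407 with an estimated correlation), with 1 member, CDC25B at -0.27, falling over the list alone. Homologous recombination and Fanconi anaemia genes (28 members, BRCA2 0.53, adjusted p = 0.179) were higher at 0.14 (adjusted p = 0.00973; adjusted p = 0.256 with an estimated correlation), 0 passing over the list alone.

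The other 5 called lists were lower, and 4 of them are described. Autophagy and lysosome genes (26 members, SQSTM1 -0.24, adjusted p = 0.202) had a median of -0.17 (adjusted p = 0.00976; adjusted p = 0.589 with an estimated correlation), with 0 members passing over the list alone. Epithelial and luminal genes (25 members, KRT19 -0.59, adjusted p = 0.0549; KRT8 -0.32, adjusted p = 0.168) had a median of -0.10 (adjusted p = 0.0109; adjusted p = 0.327 with an estimated correlation) and 5 falling over the list alone. Ribosome biogenesis and MYC target genes (33 members, SRM -0.35, adjusted p = 0.13) had a median of -0.11 (adjusted p = 0.0109; adjusted p = 0.256 with an estimated correlation) with 1 rising and 2 falling. The p53 targets (28 members, FDXR -0.49, adjusted p = 0.216) had a median of -0.10 (adjusted p = 0.0109; adjusted p = 0.389 with an estimated correlation) with 3 falling. None of the members of these 11 lists was called over all genes in the fit of 6 libraries. Log2 fold changes followed GC content across genes (Spearman -0.622 over 10766 genes, which are not independent replicates). A correction of each library for GC content and length ended the calls of the DNA repair list (median 0.02, adjusted p = 0.4) and of the epithelial list (-0.02, adjusted p = 0.263). The same correction newly called the ERK response list as higher (0.12, adjusted p = 0.0138; adjusted p = 0.191 with an estimated correlation) and lowered the medians of the G2 and mitosis list to 0.08 and of the autophagy list to -0.06, both still called.

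Without ETS1 siRNA replicate 1 the chaperone genes had 15 members that rose and 0 that fell among 21, the ribosomal proteins 41 that fell and 0 that rose among 56, called over all genes. The respiratory chain genes had 22 that fell and 1 that rose among 35 and the glycolysis genes 21 that fell and 1 that rose among 34. Of the G2 and mitosis genes 21 rose and 2 fell, and of the epithelial genes 13 fell and 0 rose. The medians of the lists were then -0.15 for the respiratory chain, 0.09 for G2 and mitosis, -0.07 for ribosome biogenesis and -0.11 for autophagy, each moved towards 0 by over 1.5 times. They were 0.15 for chaperones, -0.21 for ribosomal proteins, -0.14 for glycolysis, -0.11 for epithelial genes, 0.10 for DNA repair and -0.07 for p53 targets. The replication genes of the G1/S transition, the E2F targets held back by unphosphorylated RB, then became higher as a list (median 0.06, 14 members rising and 3 falling among 45, adjusted p = 0.000745). The TGF-beta response list was then called as lower (-0.03, adjusted p = 0.0126). All 13 list calls made without that library were lost with an estimated correlation (adjusted p = 0.174 to adjusted p = 0.511). In the fit of all 6 libraries the G1/S list had a median of 0.03 and was not called.

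The 23 lists not called with ETS1 siRNA (adjusted p = 0.0699 to adjusted p = 0.997) included the CDK4/6 and RB genes (median 0.01), G1/S genes (0.03), ETS family factors (-0.03), invasion genes described as ETS1 targets (0.09, with ITGA5 falling), ERK response genes (0.12), interferon-stimulated genes (0.04) and antigen presentation genes (-0.15). Medians of the stress and metabolic lists were -0.08 for NF-kB targets, -0.02 for ATF4 targets, -0.05 for cholesterol synthesis, 0.02 for fatty acid synthesis, -0.03 for NRF2 targets, -0.02 for BCL2 family genes and 0.04 for replication-dependent histones. Those of the identity lists were -0.04 for TGF-beta response, -0.01 for mesenchymal genes, which also hold ITGA5, 0.03 for basal genes, 0.03 for neuroendocrine genes and 0.07 for markers of leukocytes, endothelium and fibroblasts. The zinc finger cluster around ZNF783 had a median of -0.13, the corepressors of KRAB zinc finger proteins -0.03 and the small RNA silencing machinery -0.03. The chromosome 7 cluster passed without ETS1 siRNA replicate 2 (adjusted p = 0.0419) or control replicate 2 (adjusted p = 0.0371), and with a filter of 1 CPM (adjusted p = 0.0322). With the GC and length correction over all 6 libraries the median of this cluster was 0.0028 (camera adjusted p = 0.832). The sign of the median, the mean and the test differed for 9 of the uncalled lists: CDK4/6 and RB, ETS family, invasion, interferon, antigen presentation, mesenchymal, neuroendocrine, small RNA silencing and NRF2.

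The second comparison asked which transcripts differ when ZNF783 is targeted. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 1195 ± 12.6 to 842 ± 3.58 CPM (SD, n = 3 per group; log2 fold change -0.51, SE 0.023, adjusted p = 4.95e-21). The secreted metalloprotease gene ADAMTS1 fell from 129 ± 3.19 to 82.7 ± 1.75 CPM (-0.64, SE 0.034, adjusted p = 5.54e-19). DIO2 fell from 21.4 ± 1.27 to 11.8 ± 0.0993 CPM (-0.86, SE 0.076, adjusted p = 6.24e-12), and the neuropeptide precursor gene VGF from 597 ± 43.4 to 347 ± 8.06 CPM (-0.78, adjusted p = 3.28e-05). DCP2, the mRNA decapping enzyme, rose from 125 ± 5.99 to 190 ± 2.63 CPM (0.61, SE 0.032, adjusted p = 5.54e-19). DICER1, which cuts microRNA precursors, rose from 173 ± 7.76 to 248 ± 3.57 CPM (0.52, SE 0.030, adjusted p = 1.1e-17). STRADB, a pseudokinase partner of the tumour suppressor LKB1, rose from 23.3 ± 0.953 to 38.05 ± 0.708 CPM (0.71, SE 0.057, adjusted p = 3.26e-13). The other genes with the largest rises were LSM11 (0.59), ARRDC3 (0.58), CREBRF (0.55), DHRS2 (0.54), CUTA (0.53), ZNF138 (0.52) and KLHL28 (0.51). Those with the largest falls were the mucin gene MUC13 (-0.74), COL12A1 (-0.73), SEMA6B (-0.72), MFSD2A (-0.68), MISP (-0.64), C1QL4 (-0.61) and CRABP2 (-0.61), with adjusted p-values up to 0.000161. Of these, CUTA (adjusted p = 0.771) and ZNF138 (adjusted p = 0.163) lost their calls in the fit of all 12 libraries. In all, edgeR called 4428 of 17630 genes (25.1%), 1993 higher (45.0%) and 2435 lower (55.0%), with a median absolute log2 fold change of 0.195. The balance turned with scaling by library size alone, with 2298 higher (51.1%) and 2200 lower, and upper-quartile factors gave 2175 higher and 2257 lower. A change of 2-fold or more was seen in 42, 13 higher and 29 lower. STRADB, ARRDC3, CUTA, DICER1 (chromosome 14, 95086228 to 95158010, minus strand), KLHL28 and DIO2 overlap genes on the opposite strand and are uncertain.

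Among the genes of the RB axis and the others followed in each comparison, E2F1 (-0.26, adjusted p = 1e-07), MYC (-0.25, adjusted p = 3.39e-07), KLK3 (-0.51, adjusted p = 6.4e-05) and CDK4 (-0.14, adjusted p = 0.0014) fell with ZNF783 siRNA. RB1 rose from 103 ± 3.99 to 117 ± 5.52 CPM (0.18, adjusted p = 0.000136). CDKN1B rose by 0.16 (adjusted p = 3.14e-05) and CDK6 by 0.10 (adjusted p = 0.00731), the last losing its call without control replicate 2 (0.07, adjusted p = 0.0521). CCND1 (0.01, adjusted p = 0.785), CCNE1 (-0.16, adjusted p = 0.137) and CDKN1A (-0.02, adjusted p = 0.62) did not pass. With the GC and length correction CCND1 was called at 0.08 (adjusted p = 0.00143), and E2F1 (-0.14), RB1 (0.10) and CDK4 (-0.09) moved towards 0 by over 1.5 times but were still called. In the fit of all 12 libraries none of the 7 calls above held: E2F1, MYC, KLK3, CDK4, RB1, CDKN1B and CDK6 had adjusted p = 0.0536 to adjusted p = 0.675. The spread of that fit also holds ETS1 siRNA replicate 1 (common coefficient of variation 0.0795, against 0.0237 for the ZNF783 libraries alone, edgeR).

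Of the 34 lists, 11 were called with ZNF783 siRNA, and 5 of these held with an estimated correlation. Chaperones and folding genes of the endoplasmic reticulum fell together. Of 21 members 16 fell, 0 rose and 5 did not pass, with a median log2 fold change of -0.25 (adjusted p = 6.07e-33; adjusted p = 0.00424 with an estimated correlation; 17 fell when adjusted over the list alone). Examples are HSPA5 (-0.51), the disulfide isomerase gene PDIA4 (-0.50), the chaperone gene HYOU1 (-0.48) and MANF (-0.42). Genes of G2 and mitosis rose, 29 of 40, with 1 falling and 10 not passing (median 0.20, adjusted p = 2.81e-24; adjusted p = 0.00424 with an estimated correlation; 31 rising and 2 falling over the list alone). Among them were HMMR (0.46), the kinetochore genes NDC80 (0.35) and CENPF (0.31), and ANLN (0.23). The small RNA silencing machinery rose, with 7 of 13 members rising, 1 falling and 5 not passing (median 0.15, adjusted p = 1.12e-11; adjusted p = 0.0319 with an estimated correlation; 8 rising and 1 falling over the list alone). Members that rose were DICER1 (0.52), the Argonaute partners TNRC6A (0.49) and TNRC6B (0.28), and AGO2 (0.31). ATF4 targets and amino acid synthesis genes fell, 15 of 30 with 1 rising and 14 not passing (median -0.10, adjusted p = 1.09e-08; adjusted p = 0.0263 with an estimated correlation; 15 falling and 1 rising over the list alone). They included the amino acid transporter gene SLC7A5 (-0.35) and the serine synthesis genes PHGDH (-0.27) and PSAT1 (-0.23), and PCK2 (-0.30). Epithelial and luminal genes fell, 13 of 25 with 1 rising and 11 not passing (median -0.13, adjusted p = 9.84e-08; adjusted p = 0.0299 with an estimated correlation; 16 falling and 1 rising over the list alone). Those that fell included GATA2 (-0.36), the tight junction genes CLDN7 (-0.27) and CLDN4 (-0.22), and the keratin gene KRT8 (-0.26). HMMR, CENPF, ANLN, PHGDH, PCK2, CLDN7 and CLDN4 lost their calls in the fit of all 12 libraries (adjusted p = 0.0692 to adjusted p = 0.478).

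**Figure D2:**
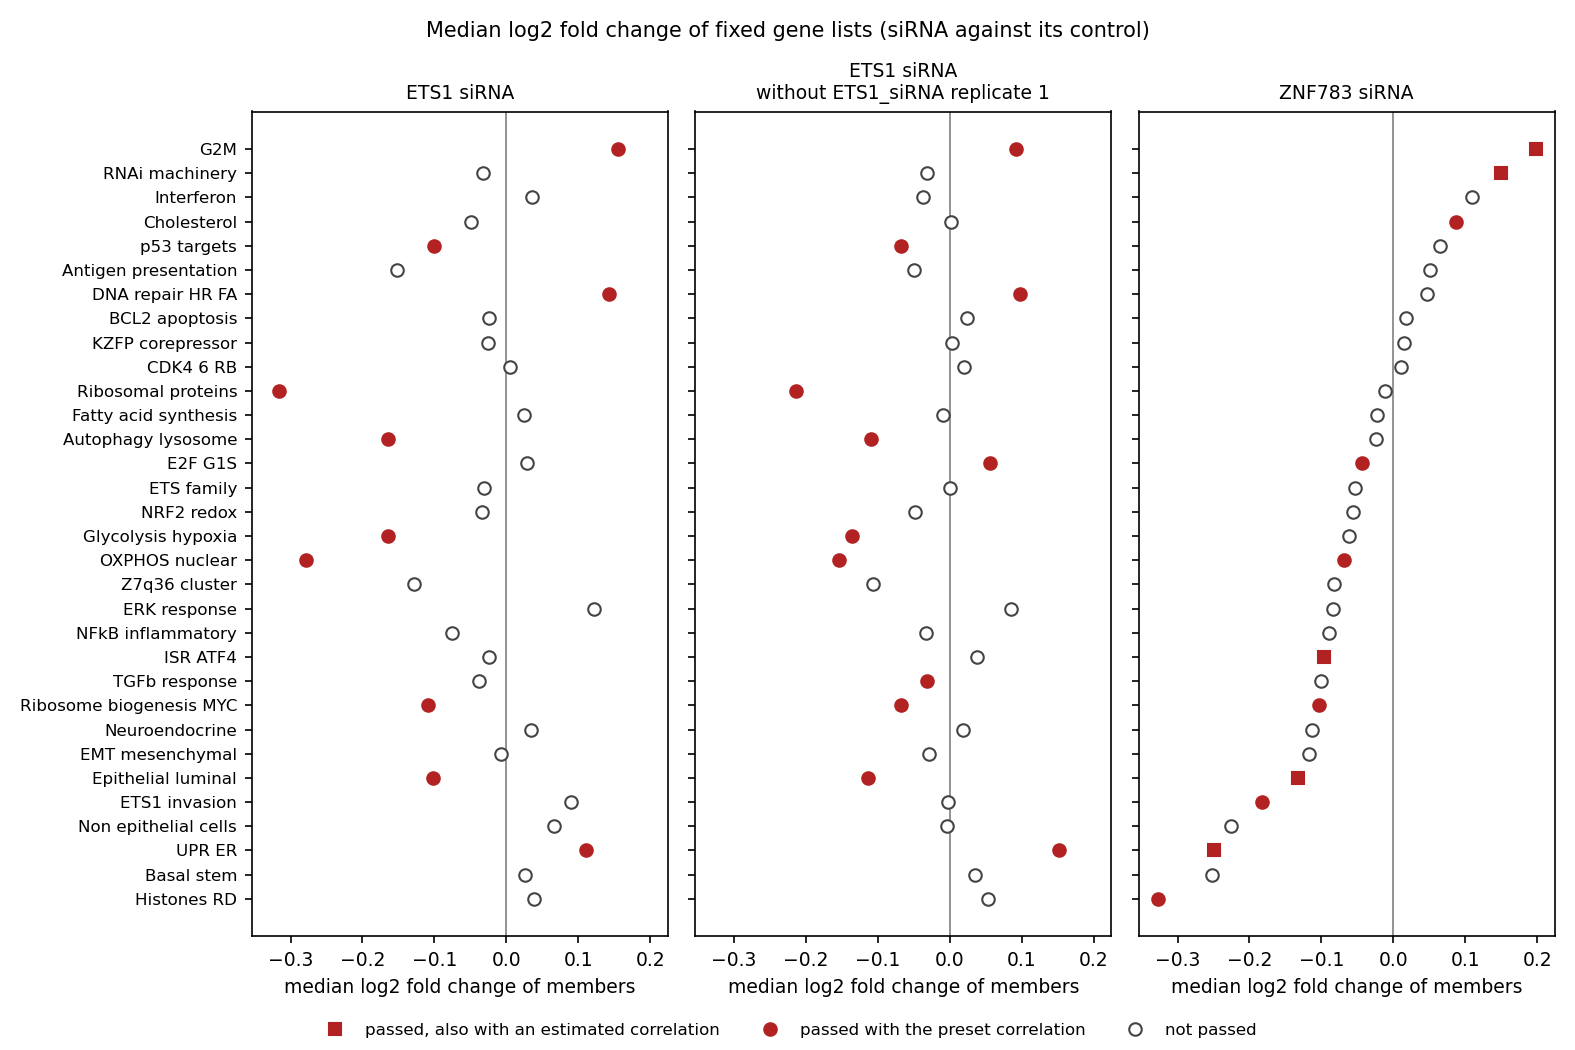
Median log2 fold change of the gene lists reported, with ETS1 siRNA (left), with ETS1 siRNA without replicate 1 (middle) and with ZNF783 siRNA (right), each against its own controls. Filled symbols mark lists called by camera at an adjusted p below 0.05 with the preset correlation, and squares those that also held with an estimated correlation. The chaperone list lies at 0.11 with ETS1 siRNA and at -0.25 with ZNF783 siRNA.

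The other 6 lists called with ZNF783 siRNA were lost with an estimated correlation, although the invasion list held with it after the GC and length correction (adjusted p = 0.0456). Cholesterol synthesis genes were higher (median 0.09, adjusted p = 5.96e-07; adjusted p = 0.102 with an estimated correlation), 11 of 24 rising and 1 falling (12 and 1 over the list alone), with HMGCS1 at 0.45, MSMO1 at 0.33 and SC5D at 0.28. Ribosome biogenesis and MYC target genes were lower (-0.10, adjusted p = 7.53e-07; adjusted p = 0.0676 with an estimated correlation), 17 of 33 falling and 1 rising (20 and 1 over the list alone), with BYSL at -0.36, RRP12 at -0.22 and CAD at -0.21. Invasion genes described as ETS1 targets were lower (-0.18, adjusted p = 0.000146; adjusted p = 0.0676 with an estimated correlation), 5 of 12 falling and 0 rising (7 falling over the list alone), among them ADAMTS1, TNC (-0.41), MET (-0.35) and ITGAV (-0.12). The G1/S genes were lower (-0.04, adjusted p = 0.017; adjusted p = 0.102 with an estimated correlation), 16 of 45 falling and 2 rising (17 and 4 over the list alone), with TK1 at -0.26, E2F2 at -0.19 and MCM3 at -0.16. Without siRNA replicate 3 their median was -0.02, still called. Respiratory chain genes were lower (-0.07, adjusted p = 0.0344; adjusted p = 0.37 with an estimated correlation), 14 of 35 falling and 3 rising (15 and 4 over the list alone), with COX4I1 at -0.17 and NDUFB5 at 0.25. The call was lost without siRNA replicate 2 (adjusted p = 0.0819) or control replicate 1 (adjusted p = 0.0692), and with a filter of 1 CPM (adjusted p = 0.0533). Replication-dependent histone genes were lower (-0.33, adjusted p = 0.0462; adjusted p = 0.19 with an estimated correlation), 3 of 12 falling and 0 rising (3 over the list alone), with H2BC21 at -0.47, H2AC6 at -0.41 and H2BC12 at -0.37. Their call was lost without siRNA replicate 3 (adjusted p = 0.0629) or control replicate 2 (adjusted p = 0.0563), and with that filter (adjusted p = 0.0533). Log2 fold changes followed GC content here too (Spearman -0.514 across 10969 genes). With the correction ITGAV stood at -0.19, while ANLN (0.14), SLC7A5 (-0.23), GATA2 (-0.21), CLDN4 (-0.13), CAD (-0.13), TK1 (-0.16), E2F2 (-0.10) and NDUFB5 (0.16) moved towards 0 by over 1.5 times, all still called. SC5D, BYSL, RRP12, CAD, ITGAV, TK1, E2F2, MCM3, COX4I1 and H2BC12 lost their calls in the fit of all 12 libraries (adjusted p = 0.104 to adjusted p = 0.293).

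The 23 lists not called with ZNF783 siRNA had adjusted p-values of 0.0525 to 0.995. Over all genes, p53 targets had 10 rising and 4 falling members (median 0.06, adjusted p = 0.0531), with CCNG1 (0.37) and SESN1 (0.43) rising and GDF15 (-0.51) falling. Basal genes had 0 rising and 5 falling (-0.25, adjusted p = 0.0525), and TGF-beta response genes 3 and 7 (-0.10, with ID1 at -0.38 and ID3 at -0.35 falling). In the same order, glycolysis genes had 7 and 14 (-0.06), neuroendocrine genes 4 and 7 (-0.11), mesenchymal genes 1 and 5 (-0.12) and ERK response genes 3 and 7 (-0.08). The CDK4/6 and RB genes had 6 rising and 6 falling (0.01), and ETS family factors 5 and 5 (-0.05). DNA repair genes had 7 and 1 (0.05), BCL2 family genes 7 and 2 (0.02), ribosomal proteins 8 and 3 (-0.01) and interferon-stimulated genes 4 and 2 (0.11). Antigen presentation had 3 and 2 (0.05), NF-kB targets 0 and 2 (-0.09), fatty acid synthesis 3 and 4 (-0.02), autophagy 4 and 4 (-0.02), NRF2 targets 4 and 3 (-0.06), the ZNF783 cluster 0 and 4 (-0.08), KRAB corepressors 4 and 3 (0.01) and non-epithelial markers 0 and 2 (-0.23). The basal and DNA repair lists were called without siRNA replicate 1 (adjusted p = 0.0258 and adjusted p = 0.0393), and the BCL2 family list without siRNA replicate 2 (adjusted p = 0.0341). Scaling by library size alone called the p53, DNA repair and basal lists (adjusted p = 0.0441 each). The GC and length correction called the p53 (adjusted p = 0.00525), BCL2 family (adjusted p = 0.0301) and basal lists (adjusted p = 0.0409), all lost with an estimated correlation (adjusted p = 0.0819 to adjusted p = 0.511). Without control replicate 1 the p53, basal and chromosome 7 cluster lists (adjusted p = 0.0435 each), the DNA repair list (adjusted p = 0.0376) and the TGF-beta list (adjusted p = 0.0406) were called. Median, mean and test differed in sign for lists that include the ETS family, ribosomal proteins, KRAB corepressors and autophagy.

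A further comparison asked where the 2 siRNAs acted differently, as the ZNF783 effect minus the ETS1 effect. ARL6IP1, a membrane-shaping protein of the endoplasmic reticulum, differed by 1.07 (SE 0.097, adjusted p = 0.000182) between them. STAT5A differed by 0.92 (adjusted p = 0.00506), the neuritin gene NRN1 by 0.82 (adjusted p = 0.00612), ZBTB34 by 0.80 (adjusted p = 0.00135) and the peroxisomal enzyme gene CROT by 0.75 (adjusted p = 0.00153), all relatively higher with ZNF783 siRNA. DIO2 differed by -1.82 (SE 0.116, adjusted p = 1.76e-05), having risen with ETS1 siRNA and fallen with ZNF783 siRNA. Other relatively lower genes were TPM4 by -1.14 (adjusted p = 0.000989), BCHE by -0.94 (adjusted p = 0.00262), the intermediate filament gene NES by -0.89 (adjusted p = 0.00348) and the matrix protein gene THBS1 by -0.88 (adjusted p = 2.56e-05). In the RB axis CDKN1A (0.44, adjusted p = 0.0335) and CCND1 (0.24, adjusted p = 0.0159) differed. ZNF783 itself did not pass (0.05, adjusted p = 0.925). The CDKN1A call was lost without any 1 of the 3 ETS1 control, 3 ZNF783 siRNA or 3 ZNF783 control libraries (adjusted p = 0.0699 to adjusted p = 0.106). The CCND1 call was lost without ETS1 control replicate 1 (adjusted p = 0.0627), ZNF783 siRNA replicates 1 (adjusted p = 0.0692) or 2 (adjusted p = 0.055), or ZNF783 control replicates 1 (adjusted p = 0.0616) or 3 (adjusted p = 0.0572). Without ETS1 siRNA replicate 1 the difference was also called for E2F1 (-0.40, adjusted p = 5.53e-09), KLK3 (-0.56, adjusted p = 0.000221), MYC (-0.19, adjusted p = 0.00139) and CCNE1 (-0.32, adjusted p = 0.0253), all relatively lower with ZNF783 siRNA. In all, 330 of 19594 genes differed (edgeR), 113 relatively higher with ZNF783 siRNA (34.2%) and 217 lower (65.8%), 23 of them by 2-fold or more. The count rose to 2735 without ETS1 siRNA replicate 1, and the balance turned, with 1484 higher (54.3%) and 1251 lower, or 1874 (58.1%) and 1353 with the GC and length correction as well. It was 140, 178 and 167 without ETS1 control replicates 1 to 3, 145, 165 and 156 without ZNF783 siRNA replicates 1 to 3, and 157, 163 and 165 without ZNF783 control replicates 1 to 3. With the GC and length correction it was 665, 334 higher and 331 lower, and with no filter 978, 500 higher and 478 lower.

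The chaperone list had the smallest adjusted p among the lists. Its members were lower with ZNF783 siRNA relative to ETS1 siRNA by a median of -0.38 (adjusted p = 1.76e-27; adjusted p = 6.17e-05 with an estimated correlation), 11 of 21 members falling and 0 rising over all genes and 16 falling over the list alone. It was the only one of 14 called lists that held with an estimated correlation in the fit of 12 libraries. Without ETS1 siRNA replicate 1 15 lists were called and 6 held with an estimated correlation: chaperones (adjusted p = 1.39e-05), ATF4 targets (adjusted p = 0.00153), G1/S genes (adjusted p = 0.00256), small RNA silencing (adjusted p = 0.00289), p53 targets (adjusted p = 0.00638) and glycolysis (adjusted p = 0.0301). Over all 12 libraries the other called lists were relatively higher for ribosomal proteins (median 0.30; adjusted p = 0.244 with an estimated correlation), p53 targets (0.18; adjusted p = 0.103 with an estimated correlation), respiratory chain genes (0.18; adjusted p = 0.408 with an estimated correlation), and cholesterol synthesis (0.17; adjusted p = 0.325 with an estimated correlation). The same direction was seen for glycolysis (0.16; adjusted p = 0.191 with an estimated correlation), small RNA silencing (0.09; adjusted p = 0.103 with an estimated correlation) and autophagy (0.07; adjusted p = 0.325 with an estimated correlation). Relatively lower were histones (-0.37; adjusted p = 0.105 with an estimated correlation), invasion genes (-0.29; adjusted p = 0.112 with an estimated correlation), basal genes (-0.24; adjusted p = 0.105 with an estimated correlation), ERK response genes (-0.15; adjusted p = 0.112 with an estimated correlation), G1/S genes (-0.10; adjusted p = 0.191 with an estimated correlation) and ATF4 targets (-0.07; adjusted p = 0.417 with an estimated correlation). The ERK call was lost without ETS1 siRNA replicate 2 (adjusted p = 0.0649) or ZNF783 control replicate 1 (adjusted p = 0.057), with a filter of 1 CPM (adjusted p = 0.0506), and with the GC and length correction without ETS1 siRNA replicate 1 (adjusted p = 0.0722). That of the ATF4 targets was lost without ETS1 siRNA replicate 2 (adjusted p = 0.11) or 3 (adjusted p = 0.107). Without ETS1 siRNA replicate 1 the medians were 0.07 for cholesterol synthesis, 0.07 for the respiratory chain, 0.20 for ribosomal proteins and -0.12 for ATF4 targets. The G1/S median was -0.06 without ETS1 siRNA replicate 2 or 3. Without ETS1 siRNA replicate 2 the medians were 0.28 for the respiratory chain and 0.10 for autophagy, and the latter was 0.12 without ZNF783 siRNA replicate 3. With the GC and length correction they were -0.15 for invasion genes, 0.14 for small RNA silencing and 0.11 for autophagy, all still called. The other 20 lists were not called (adjusted p = 0.141 to adjusted p = 0.987), the genes of G2 and mitosis among them (adjusted p = 0.276). These were called as relatively higher without ETS1 siRNA replicate 1 (median 0.08, adjusted p = 0.000376), a call lost with an estimated correlation (adjusted p = 0.106). So was the BCL2 family with the preset correlation without ETS1 siRNA replicate 3 (0.13, adjusted p = 0.0492). Median, mean and test differed in sign for 6 of these 20, among them G2 and mitosis, CDK4/6 and RB, TGF-beta response and KRAB corepressors.

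Among 17481 genes tested in both experiments, 6 were called with both siRNAs. DCBLD2, BLOC1S6 and CDK14 rose with both, CRIP2 and MARCKSL1 fell with both, and DIO2 rose with ETS1 siRNA and fell with ZNF783 siRNA. Independent lists of these sizes would share 0.57 genes higher in both (3 found, 1-sided Fisher exact p = 0.0124, adjusted p = 0.0495 over 4 directions), 0.557 lower in both (2 found, p = 0.0958, Fisher exact) and 0.696 higher with ETS1 siRNA and lower with ZNF783 siRNA (1 found). Log2 fold changes correlated across genes at r = 0.202 (Pearson) and 0.283 (Spearman). Without ETS1 siRNA replicate 1, 1908 genes were called with both, 633 higher and 951 lower in both, against 224 and 363 for independent lists. A further 161 and 163 moved in opposite directions, against 274 and 297. Those moving alike included ZNF138 and FAM217B, which rose, and OTOP3, ENTREP2 and AGPAT4, which fell. ADAMTS15, ARL6IP1, PER3 and NRN1 fell with ETS1 siRNA and rose with ZNF783 siRNA, and DIO2, MATN4, BGN and EPHA5 did the opposite. With the GC and length correction as well, 337 were higher and 549 lower in both, against 139 and 266 for independent lists. Opposite directions then also exceeded independent lists, unlike before the correction: 194 rose with ETS1 siRNA and fell with ZNF783 siRNA against 162 (Fisher exact, adjusted p = 0.0048), and 260 did the reverse against 229 (adjusted p = 0.0122). The correlation was r = 0.0435 (Pearson) and 0.0857 (Spearman). Genes are not independent replicates, so the Fisher p-values describe these libraries only.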

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

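The tests against GC content and transcript length given here, and the settings applied to the lists of the difference, were chosen after the results were seen; the depth tests and the counts of splits were set beforehand. A closer look is given to the 330 genes, those named among them and the 14 lists called in the test of the difference. This difference is stated as the ZNF783 effect minus the ETS1 effect on the log2 scale. Each siRNA was used only in its own experiment, so siRNA and experiment cannot be told apart here. Of the 14 lists, 13 lost their calls with an estimated correlation, all but the chaperones, and without ETS1 siRNA replicate 1 6 of 15 called lists held. DIO2 differed by -1.82, as it rose with ETS1 siRNA and fell with ZNF783 siRNA in all 3 libraries of each group. The tropomyosin gene TPM4 differed by -1.14, BCHE by -0.94, NES by -0.89 and the matrix gene THBS1 by -0.88, while ARL6IP1 (1.07), STAT5A (0.92), NRN1 (0.82), ZBTB34 (0.80) and CROT (0.75) lay the other way. CDKN1A (0.44) and CCND1 (0.24), which act on CDK activity in G1, also differed. Among the lists, chaperones of the endoplasmic reticulum differed by a median of -0.38, histones by -0.37, invasion genes by -0.29, basal genes by -0.24, ERK response genes by -0.15, G1/S genes by -0.10 and ATF4 targets by -0.074. Ribosomal proteins differed by 0.30, p53 targets by 0.18, respiratory chain genes by 0.18, cholesterol synthesis by 0.17, glycolysis by 0.16, small RNA silencing by 0.094 and autophagy by 0.065.

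Of 100 drawn splits of the 12 libraries, kept within each experiment, 2 gave at least 330 genes, the real split included, a share under 0.05. The other was the split that exchanges siRNA and control for the whole ZNF783 experiment; it tests the sum of both effects and called 2445 genes, which points to a structure of the samples, namely the groups themselves. The next highest split called 23 genes. All splits but the real one and that exchange put siRNA and control libraries into the same group. Any effect of an siRNA then adds to the spread and lowers the count, whether or not the 2 siRNAs differ. The share therefore cannot tell a difference between the siRNAs from an effect of either. No conclusion on the 330 genes is drawn from it.

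In the first of the patterns weighed, chaperone genes were lower and genes of G2 and mitosis higher with ZNF783 siRNA (medians -0.25 and 0.20). Differences in GC content and length are argued against as the whole cause, because after a correction for them the chaperone list had adjusted p = 5.29e-52 (median -0.26) and the mitotic list adjusted p = 1.1e-21 (0.16). Differences in depth are argued against too, as far as counting noise goes. With the 6 libraries thinned to the smallest total the camera adjusted p-values were 8.97e-33 (-0.24) and 1.67e-24 (0.20). Thinning keeps the expected share of each gene, so it tests no other effect of depth. What stays open, untested, is an effect of the siRNA on other transcripts, given that ZNF783 stood at 80.5% of control, and a difference between the cultures. That targeting ZNF783 lowers chaperone and raises mitotic transcripts may be held as a hypothesis only, found and tested on the same libraries. A mitotic rise particular to ZNF783 siRNA was not shown. The mitotic list was also higher with ETS1 siRNA (median 0.16, camera adjusted p = 0.000331, or 0.407 with an estimated correlation). Its difference between the siRNAs was not called over 12 libraries (camera adjusted p = 0.276). Without ETS1 siRNA replicate 1 that difference was called (0.08, camera adjusted p = 0.000376, or 0.106 with an estimated correlation).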

How the results depend on the processing

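The GC and length corrections, the quality weights, the overlap without ETS1 siRNA replicate 1 and all settings of the difference lists were chosen after the data were seen. The 9 genes called with ETS1 siRNA became 253 with no filter, 734 with DESeq2, 23 with limma-voom, 1875 in the fit of all 12 libraries, 28 with the correction, 4010 with the correction and without ETS1 siRNA replicate 1, 3734 with quality weights (replicate 1 weighted at 0.0931), and 0 at an adjusted p below 0.01 or at 2-fold (edgeR, 3535 at an unadjusted p under 0.05); leaving out 1 library gave 0 to 4649, the latter without ETS1 siRNA replicate 1. The other scalings and the filter at 1 CPM gave 9 to 13. The 4428 genes called with ZNF783 siRNA became 2718 with DESeq2, 824 in the fit of all 12 libraries, 2931 at an adjusted p below 0.01 and 42 at 2-fold, and stayed at 3450 to 4498 otherwise (3485 to 4127 with 1 library left out). The 330 genes of the difference became 978 with no filter, 663 with DESeq2, 665 with the correction, 3227 with the correction and without ETS1 siRNA replicate 1, 100 at an adjusted p below 0.01 and 23 at 2-fold (140 to 2735 with 1 library left out). The 6 genes called with both siRNAs became 0 at 2-fold, 283 with DESeq2 and 1908 without ETS1 siRNA replicate 1. In the fit of all 12 libraries each knockdown takes its spread from both experiments, by construction. The common coefficient of variation between replicates (edgeR) was 0.0795 there, 0.0252 without ETS1 siRNA replicate 1 and 0.0237 for the ZNF783 libraries alone. Calls of ZNF783 siRNA lost in that fit were thus set against a spread raised by 1 library of the other experiment. For the ETS1 libraries alone the coefficient was 0.107. ETS1 siRNA effects were thus set there against a spread lowered by the ZNF783 libraries, and the 1875 calls carry this limit. The cause of the other shifts was not tested. Of 11 lists each, 0 held with an estimated correlation for ETS1 siRNA and 5 for ZNF783 siRNA; other settings gave 10 to 14 and 9 to 15. The ATF4 list with ETS1 siRNA turned from a median of -0.02 to 0.065 (adjusted p = 0.000968; adjusted p = 0.196 with an estimated correlation) with the correction and without replicate 1; the cause was not tested. Of the named genes, 67 of 79 were newly called with ETS1 siRNA without replicate 1. The 9 called lost their calls when any other library of that experiment was left out. The 79 include the highest and lowest genes called without replicate 1, so the 67 were partly fixed in advance. The other counts out of the 79 rest on the same picked genes. With ZNF783 siRNA 29 of 72 lost their calls in the fit of all 12 libraries and 1 without control replicate 2. DESeq2 newly called 40 of the 79, limma-voom 5 and the fit of all 12 libraries 58, and the correction 4, while 3 were lost. In the simulations edgeR recovered the smallest change drawn for 4.48% of genes with ETS1 siRNA and 94.0% with ZNF783 siRNA. Small changes were thus mostly out of reach of the edgeR fit of all 6 ETS1 libraries. Without ETS1 siRNA replicate 1 this limit did not hold, as called genes had a median absolute log2 fold change of 0.187. ZNF783 stood at 81.1% of control by library size alone.

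A pairing of the libraries by replicate number was not shown. Deviations of same-numbered siRNA and control libraries from their group means correlated at 0.104, -0.236 and 0.295 in the ETS1 experiment. In the ZNF783 experiment they correlated at -0.102, -0.0647 and -0.0522. Only replicate 3 of the ETS1 experiment correlated best with its own number. The ETS1 siRNA mean includes the outlying replicate 1, which enters every deviation of that group, so a pairing there cannot be excluded. With the replicate number as a block, 0 genes were called with ETS1 siRNA (edgeR, 3139 at an unadjusted p under 0.05), 4476 with ZNF783 siRNA, 54 for the difference and 0 with both siRNAs, and 11 lists in each experiment, and 4 of the 22 genes named for the difference lost their calls.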

Other observations

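The searches for 7-base sites, the microRNA family test, the base composition tests, the GC and length test and the knockdown test were chosen after the results were seen; the depth test and the counts of splits were set beforehand. Zinc finger genes, counted as all symbols made of ZNF and a number, were not among the lists fixed beforehand and were not tested as a list. With ZNF783 siRNA 115 rose and 22 fell among 438 tested (edgeR, median log2 fold change 0.11, against 0.00 for all genes). Of all 17630 genes 1993 rose and 2435 fell. DESeq2 called 66 zinc finger genes as higher and 10 as lower. The median lay at 0.11 to 0.12 under the other scalings and at 0.09 with the GC and length correction, where 81 rose and 8 fell. In the fit of all 12 libraries 10 rose and 4 fell. With ETS1 siRNA 0 of 447 zinc finger genes were called over 6 libraries (edgeR; DESeq2 called 39, 36 of them higher, and limma-voom 0) at a median of 0.08, and without ETS1 siRNA replicate 1 85 rose and 40 fell among 448 (median 0.03). The correction gave a median of 0.044 over 6 libraries, and of 0.0083 without replicate 1, where 62 rose and 28 fell, and in the fit of all 12 libraries 57 rose and 11 fell. The difference between the siRNAs was called for 3 zinc finger genes of 446, 2 relatively higher with ZNF783 siRNA and 1 lower. Leaving out ETS1 siRNA replicate 1 raised this to 44 higher and 21 lower, or 51 and 19 with the correction as well.

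The second pattern is that ETS1 siRNA replicate 1 stood apart, its genes lying 7.001 times as far from the mean of replicates 2 and 3 as these lay from each other, with both distances scaled to the same variance. GC content and length are argued against as the whole cause, since the ratio was 6.08 after the correction against at most 1.14 in the other 11 libraries, and lower depth likewise, since it was 5.80 after thinning against at most 1.23 in the other 5. Whether ETS1 was lowered to another degree in this library cannot be told apart from an equal knockdown. ETS1 had at most 3 counts in the 3 siRNA libraries and 0, 1 and 0 in their controls. No knockdown could therefore be measured in any of them. A different culture, harvest or labelling of this library stays open, untested. No biological explanation was tested, as the labels give replicate 1 no condition of its own.

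The third pattern is that genes with certain sites in their 3' UTR shifted together, as pairing with the seed of a small RNA would give, the lowest of 15773 sites with ETS1 siRNA being GGTGCCC (z -7.99, or -8.73 without replicate 1). Base composition cannot be told apart from an effect of the site itself, here or for the microRNA sites below, although other sites of the same bases had a median z of -0.738 here and of 0.10 there, because all z values had already been adjusted for GC content. Pairing with the seed of the siRNA, whose sequence is not given here, cannot be told apart from another difference between libraries: the site lowest in 4 libraries was tested in only 1 siRNA and 1 control library left over (z = -5.05 for GGTGCCC with ETS1 siRNA, where the siRNA library is replicate 1, and z = -2.06 for CCCACCC with ZNF783 siRNA), while pairs of libraries of the same group reached 2.76 and 2.57 in size. With ZNF783 siRNA the highest site was GCACTTT (z 5.63), which matches the seed of an abundant microRNA family, and sites of 13 families of epithelial cells, leaving out those seen first, had a mean z of 1.80 (12 above 0) against 0.586 for 5 families of other tissues (1-sided exact permutation p = 0.0508), so that weaker microRNA repression stays undecided. Of the 10 splits of each experiment, 4 gave a z as far from 0 with ETS1 siRNA (7.99; highest other 9.43, at CCACCCC, where ETS1 siRNA replicate 1 was grouped with 2 controls, a structure of the samples) and 1 with ZNF783 siRNA (5.63; highest other 5.48), and 10 splits are too few for a share under 0.05.

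The same 10 splits are too few for a share under 0.05 for the counts of genes and lists. For ETS1 siRNA the real split gave 9 genes (highest other 0) and 11 lists (highest other 5), and for ZNF783 siRNA 4428 genes (highest other 1) and 11 lists (highest other 9); in each case 1 split, the real one, gave as many.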
